A study of Mus musculus with 96 samples.

How the data were processed

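RNA of T cells from mice was measured on 48 Affymetrix Mouse Exon ST arrays. The mice were either wildtype (wt) or homozygous for thunder (thu), a point mutation of Hnrnpll, which encodes a heterogeneous nuclear ribonucleoprotein that regulates splicing. Per the labels, CD4 and CD8 single positive thymocytes were sorted from the thymus, and naive (CD44lo) and memory (CD44hi) CD4 and CD8 T cells from spleen and lymph node by staining for CD4, CD8 and CD44. This makes 6 cell subsets, 2 genotypes and 12 groups, with 4 independent RNA pools in each group according to the series text. The pools are the replicates, so gene-level p-values rest on the spread between pools of animals, taken over all groups.

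Each array was deposited as an exon-level record of 193380 probesets and a gene-level record of 23207 transcript clusters, which gives 96 records. The deposited values are on the log2 scale, per the labels and the values themselves. The submitters' processing notes name RMA, and the series text names Partek Genomics Suite 6.3 with the core probesets of the array. According to the same text the authors kept 15788 genes with a mean signal above 3 and tested each subset by an analysis of variance on genotype and probeset. Each subset's 8 arrays share nearly the same mean probeset signal (range at most 0.00657 on the log2 scale) while that mean differs between subsets, from 4.77 in thymus CD8 to 6.35 in naive CD4. The subsets were therefore treated as normalized separately. Memory against naive crosses these scales, and its values carry a median shift of -0.26 in CD4 and -0.20 in CD8 cells.

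Transcript clusters were named through the platform annotation, with symbols updated against the GRCm38 gene table. At the gene level 14939 clusters had 1 symbol, 989 had several and 7279 had none. Of the probesets 178786 had 1 symbol, 1318 had several and 13276 had none, and 2036 symbols were updated. Only features with 1 symbol are named. No probeset coordinates were used here, so exons and genome positions are not given, and 2 planned results on the variable exons of Ptprc in memory CD4 and CD8 cells are not given here.

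Gene-level comparisons used limma 3.58.1 in R 4.3.3 on the log2 values of 21739 clusters with a mean above 3, of which 14400 have 1 symbol. A single model with 1 mean per group over all 48 arrays gave every contrast, with p-values adjusted by the Benjamini-Hochberg method and a threshold of 0.05. Standard errors (SE) of changes come from this model and standard deviations (SD) from the 4 arrays of a group. Splicing was tested with limma's F test for differences between the probesets of a gene (diffSplice) on the 8 arrays of a subset (or the 8 wt arrays of a lineage, or 16 arrays of a lineage for genotype by memory), over 162698 probesets of 14332 genes with at least 2 probesets. A probeset's deviation is its log2 change minus the mean change of the gene's other probesets. The F test pools the spread over the probesets of a gene as if they were independent, although they share arrays. Its p-values therefore do not measure the spread between pools alone and can be too small. Both models take same-numbered arrays as independent unless the replicate block is named. These choices, the gene lists and the rule for named genes were made before the data were examined. The number of arrays limits the precision of every value.

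The rule names Hnrnpll and Ptprc in every comparison. At the gene level it takes the 10 largest rises and falls past the threshold without overlap between the 4 and 4 arrays, or 5 and 5 in thymus and naive subsets. For splicing it takes the 10 genes of smallest adjusted p, or 5 in thymus and naive subsets, each with its most deviating probeset. For each fixed list it takes the count of members that rose or fell with up to 4 examples. A gene named outside the rule is said to be chosen after its values were seen.

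The 24 fixed lists cover memory and effector genes, naive T cell genes, regulatory T cell genes, follicular helper and exhaustion genes, immature thymocyte genes, genes of mature thymocytes ready to leave, cell cycle, the hnRNP family, SR and other splicing factors, genes spliced alternatively in T cells, T cell receptor signalling, apoptosis and survival, interferon-stimulated genes, immediate early and stress genes, and ribosomal genes. Marker lists of cells other than the sorted subset cover B cells, myeloid cells, dendritic cells, NK and innate-like T cells, gamma delta T cells, erythroid cells and platelets, the CD4 and CD8 lineages, and stroma and epithelium. Each list was tested with limma's camera (preset correlation 0.01, two-sided, adjusted over all lists and comparisons), and again with a correlation estimated from the residuals.

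The tests were run on simulated data made from the real means and spreads, with 100 features changed by 1 log2 and 100 by 2. Noise was drawn independently for each feature and array. Differences between whole arrays were therefore not simulated, and the real tests may make more false calls than the simulated ones. The gene-level model recovered 45 to 69 of the 100 smaller changes and 91 to 96 of the 100 larger ones in the 6 genotype comparisons, with 4 to 20 false calls. For genotype by memory it recovered 29 and 30 of the smaller and 76 of the larger changes in each lineage. With equal spread among the probesets of a gene, the F test made 2, 1, 7, 4, 7 and 9 false calls in the genotype comparisons of thymus CD4, thymus CD8, naive CD4, naive CD8, memory CD4 and memory CD8. With each probeset's own spread it made 94, 81, 103, 93, 113 and 94, because it pools the spread within a gene, and with spreads moderated across probesets it made 30, 22, 36, 64, 22 and 33. Memory against naive splicing was not simulated.

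A test that keeps each probeset's own moderated spread was therefore added after the simulation. In the same order of comparisons it made 0, 0, 1, 2, 0 and 1 false calls, and it recovered 0, 0, 38, 24, 22 and 51 of the 100 changes of 2 log2, so a count of 0 from it in the thymus carries no information. With equal spread it recovered 0, 0, 60, 0, 12 and 51, and with moderated spreads 0, 0, 74, 30, 38 and 74. Its count of 0 in naive CD8 cells may therefore carry little information too. Fitted to all 48 arrays it recovered 59 of 100 such changes in naive CD4 and 55 in memory CD4 cells, with 2 and 5 false calls.

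Pairing by replicate number was checked by correlating the deviations of same-numbered arrays from their group means. Every pair exceeded 0.1 in thymus CD8 (gene level 0.18 to 0.82, exon level 0.16 to 0.81), between naive and memory wt CD4 cells (0.11 to 0.43 and 0.11 to 0.38), and between naive and memory wt CD8 cells at the gene level (0.12 to 0.41). Naive and memory thu cells exceeded it too (gene level lowest 0.46 in CD4 and 0.17 in CD8). In these groups the numbers were taken to pair the arrays, as a hint from the data, since the labels tie them to no animal. Replicate arrays correlated at 0.785 to 0.985 and no pair was identical.

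Alternatives were the filter on low values (none, or a mean above 5), quantile normalization over all 48 arrays, only the groups compared or all 48 arrays in the fit, the replicate block, limma's Simes test and an analysis of variance without moderation for splicing, and leaving out each array. Further ones were chosen after the data were seen, namely the own-spread test, the list tests of genotype by memory with the replicate block, the joint regrouping of naive CD4 and CD8 arrays, splicing without genes changed by over 1 log2, and leaving out 8 arrays whose interquartile range lay over 0.25 log2 below the median of their subset. Those 8 arrays are thu naive CD4 1 and 2, thu naive CD8 1, thu memory CD4 1 and 2, thu and wt thymus CD8 C and wt thymus CD4 C. The other tools were version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.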

Results

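The data describe 6 T cell subsets from wt mice and mice homozygous for thunder, with 4 arrays for each subset and genotype and 48 arrays in all. Every array gives log2 signals for 23207 transcript clusters and for 193380 probesets, which are groups of probes within an exon. The subsets were treated as normalized separately, so thu and wt were compared within each subset. Changes from naive to memory cells are printed relative to the median change of all clusters, while limma tested the change as deposited, so its calls and p-values do not take the median shift into account.

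Hnrnpll and Ptprc were looked at first. Hnrnpll carries the thunder mutation, and Ptprc encodes CD45, the T cell phosphatase whose variable exons Hnrnpll is known to regulate. Hnrnpll RNA differed between thu and wt by 0.38 in thymus CD4, 0.46 in thymus CD8, 0.082 in naive CD4, 0.40 in naive CD8, 0.29 in memory CD4 and 0.90 in memory CD8 cells (log2, SE 0.37, n = 4 against 4), and limma called none of these. In memory CD8 cells it was 7.09 ± 0.53 (SD) in thu and 6.20 ± 0.13 in wt arrays. Among thu CD4 arrays it varied more, at 7.74 ± 0.99 in naive and 8.10 ± 1.18 in memory cells. The wt arrays were at 7.66 ± 0.14 and 7.81 ± 0.14. The SE is shared over all groups and does not show this. A point mutation need not change the amount of RNA, so these levels do not check the genotype labels. Ptprc RNA differed by -0.067, 0.13, -0.33, -0.17, -0.26 and -0.097 in the same order (SE 0.19), and none of these differences passed the test.

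The first question was which genes differ in amount between mutant and wildtype cells. Acp2, which encodes a lysosomal acid phosphatase, fell in thu cells of 5 subsets and was lower in all 6. In memory CD4 cells it was 5.82 ± 0.22 in thu and 8.20 ± 0.41 in wt arrays, a change of -2.38 on the log2 scale (SE 0.18, limma adjusted p = 2.1e-11). It changed by -2.11 in memory CD8 (adjusted p = 9.53e-10), -1.74 in thymus CD4 (adjusted p = 2.41e-07) and -1.46 in naive CD4 cells (adjusted p = 9.34e-06). In naive CD8 cells, where it was chosen after its values were seen, it changed by -1.35 (adjusted p = 0.000132). The change of -0.54 in thymus CD8 cells was not called. With only the compared groups in the fit, Acp2 passed in naive CD4 and memory CD4 cells and not in thymus CD4, naive CD8 or memory CD8 cells.

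**Figure D1:**
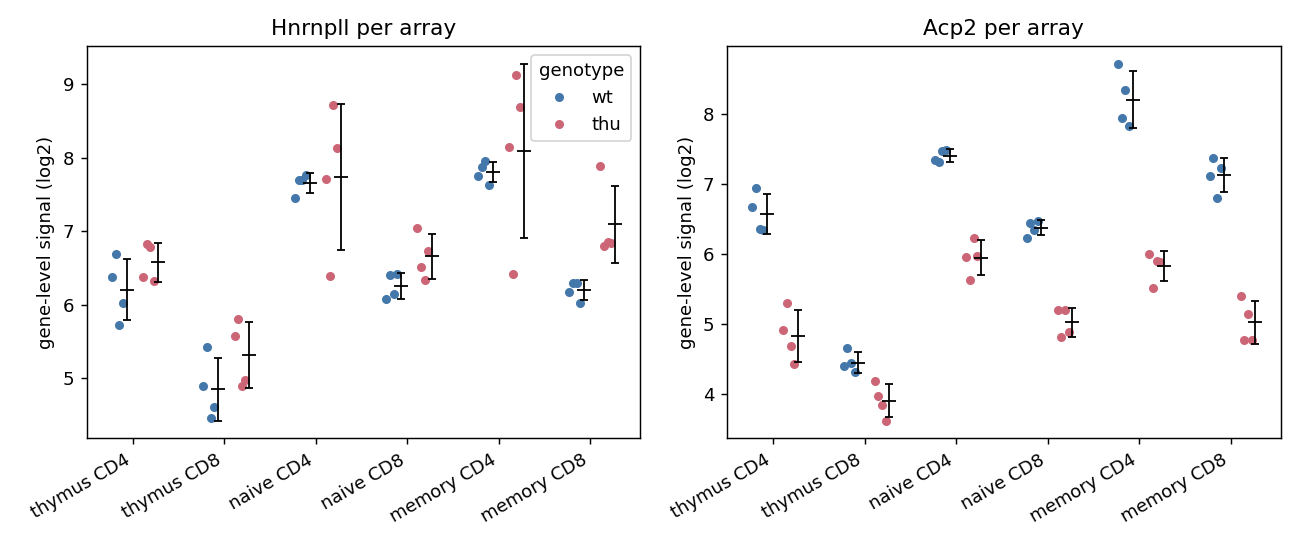
Gene-level log2 signal (vertical axis) of Hnrnpll and Acp2 in thu and wt cells of the 6 subsets, with 1 point per array and the mean ± SD of each group of 4. Acp2 is lower in thu in every subset, from 5.82 against 8.20 in memory CD4 to 3.90 against 4.44 in thymus CD8 cells.

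In CD4 single positive thymocytes Acp2 was the only cluster of 21739 that passed the test, and 325 had an unadjusted p under 0.05. Quantile normalization gave 2 clusters, and the fit of the compared groups alone gave 0. No member of any fixed list passed. As groups, immature thymocyte genes had a median change of -0.41 relative to all clusters (camera adjusted p = 0.00656; adjusted p = 0.846 with an estimated correlation), hnRNP genes -0.20 (0.0196) and B cell genes -0.56 (0.00245; adjusted p = 0.930 with an estimated correlation). Immediate early genes had a median of 0.22 (0.00434; adjusted p = 0.752 with an estimated correlation, the lowest of the 24 lists).

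In CD8 single positive thymocytes 1 cluster without a gene name was higher in thu and none was lower, and 251 clusters had an unadjusted p under 0.05. The replicate numbers paired these arrays, and limma with the replicate block called 0 clusters, as did the fit of the 2 groups alone. Naive T cell genes had a median relative change of -0.34 (camera adjusted p = 1.92e-05; adjusted p = 0.152 with an estimated correlation). T cell receptor signalling genes had a median of -0.20 (5.41e-06; adjusted p = 0.640 with an estimated correlation), and genes of mature thymocytes ready to leave had -0.23 (0.00245; adjusted p = 0.671 with an estimated correlation). With the replicate block the preset test also called the memory and effector (adjusted p = 0.0269), cell cycle (0.00328), interferon (0.0148), B cell (0.0191), myeloid (0.0294) and dendritic (0.0318) lists. With the block and an estimated correlation none of these held (adjusted p = 0.567, 0.641, 0.568, 0.449, 0.567 and 0.449). No list member passed the gene-level test.

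In naive CD4 cells thu arrays had lower Rnf32, a RING finger gene (4.40 ± 0.23 against 6.65 ± 0.63; change -2.24, SE 0.24, limma adjusted p = 4.84e-07), and lower Ovgp1, which encodes oviductin (4.76 ± 0.21 against 6.21 ± 0.41; change -1.45, adjusted p = 9.34e-06). Sbf2 and the chitinase-like gene Chil5 fell by 1.03 and 1.00. Il12rb1, which encodes a subunit of the interleukin 12 receptor, rose from 5.11 ± 0.02 to 6.19 ± 0.30 (change 1.08, SE 0.23, adjusted p = 0.0226), and the corepressor gene Spen rose from 7.38 ± 0.16 to 8.21 ± 0.17 (change 0.83, SE 0.20, adjusted p = 0.0487). In all 2 clusters rose and 75 fell, of which 15 have 1 gene symbol, and 1969 had an unadjusted p under 0.05. The 77 called clusters have a median log2 mean of 3.45, near the filter at 3. A filter at a mean above 5 gave 1 call, and leaving out 1 array gave 13 to 293. With the 2 groups alone in the fit 6 passed, 3 higher and 3 lower, without Rnf32, Il12rb1, Spen, Sbf2 or Chil5. After quantile normalization 15 clusters passed, 13 of them among the 77, and Il12rb1, Spen, Sbf2 and Chil5 were not called (adjusted p = 0.088, 0.0658, 0.204 and 0.544), nor were they without the 2 thu arrays of narrow spread, which leaves 4 clusters, all lower. Cell cycle genes had a median relative change of 0.53 (camera adjusted p = 0.000554; adjusted p = 0.930 with an estimated correlation). Follicular helper genes had a median of 0.30, hnRNP genes -0.30, ribosomal genes -0.40, B cell genes -0.75 and myeloid genes -0.79 (adjusted p = 0.809 with an estimated correlation). None of the 6 held with an estimated correlation (lowest adjusted p = 0.665) and no member passed. Adjusted over the list alone, 1 gene each rose in the regulatory T cell, follicular helper and apoptosis lists.

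In naive CD8 cells Bcl3, a coactivator of NF-kappaB, rose from 7.09 ± 0.18 to 8.12 ± 0.30 in thu (change 1.03, SE 0.20, limma adjusted p = 0.0165). Rnf32 fell by 1.42 (adjusted p = 0.00313). Prss12, which encodes the protease neurotrypsin, fell by 1.47, Dnajc19, of mitochondrial protein import, by 1.38, Metap1d, a mitochondrial methionine aminopeptidase, by 1.37, and 4632404H12Rik by 1.37. One cluster rose and 48 fell, 21 of the 49 with 1 gene symbol, and 2798 had an unadjusted p under 0.05. Quantile normalization kept 7, without Prss12, Dnajc19, Metap1d or 4632404H12Rik (adjusted p = 0.108, 0.245, 0.138 and 0.135), the fit of the 2 groups alone called 0, and without the thu array of narrow spread, replicate 1, 5 passed, all lower. Bcl3 was not called without that array (adjusted p = 0.119), nor without thu replicate 2 (0.0837) or wt replicate 3 (0.0563), so its call depends on single arrays. The naive CD4 and CD8 results share 10 clusters, all lower in both or higher in both. Independent lists would share 0.174, but both results come from 1 model, and same-numbered thu arrays of naive CD4 and CD8 cells correlated at -0.077 to 0.51. With same-numbered arrays of both lineages regrouped together, a test chosen after the results were seen, the other 34 groupings shared 0 and called 0 in naive CD8 cells. The excess is therefore not taken as a shared effect. Cell cycle genes had a median relative change of 0.44, interferon-stimulated genes 0.34 (adjusted p = 0.878 with an estimated correlation), immediate early genes 0.28 and stroma genes 0.25. None held with an estimated correlation (lowest adjusted p = 0.668), and no member passed. Adjusted over the list alone, 2 memory and effector genes and 1 interferon gene rose.

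In memory CD4 cells Acp2 was the only cluster called, with 1456 at an unadjusted p under 0.05. Without the narrow arrays 5 clusters passed, 4 higher and 1 lower, and without wt replicate 4 there were 11, all lower. In memory CD8 cells Acp2, Rnf32 and 2 clusters without a gene name fell, with 865 at an unadjusted p under 0.05. Rnf32 was 3.95 ± 0.39 in thu and 5.24 ± 0.67 in wt memory CD8 arrays (change -1.29, limma adjusted p = 0.0336), and quantile normalization ended this call (adjusted p = 0.139). Myeloid genes had a median relative change of -0.54 in memory CD4 (adjusted p = 0.930 with an estimated correlation) and -0.73 in memory CD8 cells (camera adjusted p = 1.24e-05; adjusted p = 0.593 with an estimated correlation). NK and innate-like genes had -0.44 and -0.53 (adjusted p = 0.665 and 0.167 with an estimated correlation). The preset test also called naive T cell genes (-0.28) and alternatively spliced genes (-0.23) in memory CD4 cells. In memory CD8 cells it called regulatory T cell (0.42), T cell receptor signalling (0.17), interferon (0.23), immediate early (0.15), B cell (-0.64) and CD4 lineage genes (0.85), of which the last had an adjusted p of 0.730 with an estimated correlation. No call held with it (lowest adjusted p = 0.665 in memory CD4 and 0.167 in memory CD8 cells), and no member passed at the gene level. Adjusted over the list alone, 2 apoptosis genes rose and 1 NK gene fell in memory CD8 cells.

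The second question was which genes differ in the use of their probesets between thu and wt, given that Hnrnpll regulates splicing. In naive CD4 cells the strongest gene was Thada, whose probeset 4338831 lay 2.72 lower in thu than its other probesets would give (deviation -2.72, SE 0.19, limma F test adjusted p = 3.59e-16). The same probeset deviated by -2.69 in memory CD8 cells, where Thada was again first (adjusted p = 1.58e-06), and by -3.76 in thymus CD4, -2.69 in thymus CD8, -2.71 in naive CD8 and -3.06 in memory CD4 cells. Thada lies on the chromosome of Hnrnpll, and a linked variant under this probeset is considered further below. Acp2 probeset 4731391 deviated upward by 2.35 in thymus CD4, 0.95 in thymus CD8, 1.68 in naive CD4, 1.66 in naive CD8, 2.49 in memory CD4 and 2.06 in memory CD8 cells, and the F test called Acp2 in 5 subsets, Thada in 4 and Mthfsd in 4. All Acp2 probesets together changed by -1.78 in thymus CD4, -2.46 in memory CD4 and -2.15 in memory CD8 cells. This probeset thus changed little while the gene fell. A probeset that does not follow the amount of its gene would give this too, so it is not taken as splicing. The values of Thada and Acp2 outside the subsets where the rule names them, and Mthfsd, were chosen after they were seen. The F test called 1208 genes in at least 1 subset, 126 in at least 2 and 16 in at least 3. Same-numbered arrays of different subsets are not independent, so these counts are not taken as a repeated effect. At the exon level those of memory CD4 and CD8 cells correlated at 0.061 to 0.46 in wt and 0.16 to 0.29 in thu.

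In thymus CD4 cells the F test called 3 of 14332 genes, with 41 at an unadjusted p under 0.05. They are Myo6, an unconventional myosin (probeset 5257512, deviation -1.84, SE 0.25, adjusted p = 4.02e-06), Acp2 (adjusted p = 0.0431) and the inflammasome sensor Nlrp1a (probeset 4929202, 2.69, SE 0.55, adjusted p = 0.0431). Ptprc probeset 4667430 deviated by 1.49 (SE 0.33), and the F test did not call Ptprc. In thymus CD8 cells the F test called 0 genes, with 17 at an unadjusted p under 0.05, the Simes test called 2 and the F test with the replicate block 1. Fitted to all 48 arrays, the own-spread test called 2 genes in thymus CD4 (Thada and Ptprc) and 4 in thymus CD8 (Cnot8, Ugcg, Rassf3 and Thada), all chosen after their values were seen. Within each subset it called 0. On simulated data with unequal probeset spread the F test made 94 and 81 false calls in these subsets, and other groupings of the real arrays gave up to 1286 and 4486 calls.

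In naive CD4 cells the F test called 963 genes. After Thada came Ncor1, a nuclear receptor corepressor (probeset 5502165, deviation -1.42, SE 0.20), Khdc4 (4536847, -2.54, SE 0.28), the translation initiation scaffold Eif4g1 (4531764, -2.31, SE 0.22) and the cofilin phosphatase Ssh2 (5470482, 1.11, SE 0.15). Ptprc was also called, with probeset 4667430 higher by 1.09 (SE 0.20, adjusted p = 2.66e-06), and not by the own-spread test. The 963 are out of 14332 genes tested and have a median of 15 probesets, against 9 over all genes tested. The list counts of splicing calls, here and below, were not tested against the share of all genes called. Of 27 genes spliced alternatively in T cells 4 were called, namely Ptprc, Bcl2l11, Foxp1 and Add3 (6 adjusted over the list alone). The called members of other lists were 5 of 27 for cell cycle (with Top2a and Kif11), 4 of 28 for T cell receptor signalling (Csk, Vav1, Plcg1 and Nfatc1), 3 of 18 for hnRNPs (Hnrnpm, Hnrnpu and Ptbp3) and 3 of 26 for splicing factors (Srsf1, Srsf11 and Khdrbs1; 4 adjusted over the list alone). Naive T cell genes had 3 of 15 (Satb1, Foxp1 and Actn1), immediate early genes 2 of 20 (Atf3 and Klf4), apoptosis genes 1 of 20 (Bcl2l11; 2 adjusted over the list alone) mature thymocyte genes 1 of 8 (Ms4a6b) and myeloid genes 1 of 14 (Lyz1; 2 adjusted over the list alone). Without the 2 thu arrays of narrow spread 153 genes were called, and with all 48 arrays in the fit 25. The own-spread test called 0, with 2872 genes at an unadjusted p under 0.05 in the F test and 1332 called by Simes, and the F test made 103 false calls on simulated data. Those data lack differences between whole arrays, and other groupings of the real arrays gave up to 522 calls.

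In naive CD8 cells the F test called 247 genes, led by Emc10, of the endoplasmic reticulum membrane complex (probeset 5077582, deviation 1.94, SE 0.27, adjusted p = 1.68e-08), and Prss12 (5082930, -2.15, SE 0.40). The corepressor Tle1 (5234161, 2.16, SE 0.37), Aprt, of purine salvage (4547738, 1.87, SE 0.36), and the cyclic AMP phosphodiesterase Pde8a (4456240, 2.10, SE 0.31) followed. Ptprc was not called. From the lists Gzmk, Satb1, Tpx2, Cd247 and, from the CD8 lineage, Runx3 passed, and adjusted over the list alone 3 apoptosis genes did. Naive CD4 and naive CD8 cells shared 77 called genes, where independent lists would share 16.6 and the other 34 joint regroupings shared 7 at most with fewer calls. Arrays of the same number are not independent here, so this excess is not taken as a shared effect either. The own-spread test called 0 genes, against 1614 at an unadjusted p under 0.05 in the F test and 478 by Simes, and the F test made 93 false calls on simulated data.

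In memory CD4 cells 57 genes were called, led by the death-associated kinase Dapk1 (deviation 1.39, SE 0.31, adjusted p = 0.0017) and Zmym3 (1.45, SE 0.33). Heatr5a (1.44), Acp2 (2.49, SE 0.39), Aknad1 (-1.67), the Mediator subunit Med14 (1.55), B230219D22Rik (1.71), the stress transcription factor Atf6b (1.32), the histone demethylase Kdm2a (2.78, SE 0.35) and Mcph1 (1.77) followed. Leaving out 1 array gave 0 to 329 genes, and 6 of 35 groupings gave as many as the real one, with 2106 at most. The Zmym3 probeset was -1.27 in wt replicate 1, against 0.39 to 0.71 in the other wt arrays. In memory CD8 cells 84 genes were called, where 5 of 35 groupings gave as many and leaving out 1 array gave 20 to 221. After Thada came Emc10 (1.88, SE 0.31), Tmem234 (-2.21), Zfp619 (-1.48), Slc37a2 (1.47), Acp2 (2.06, SE 0.37), Ttc25 (-2.23), Cdc42bpb (-1.96), the spectrin gene Sptbn1 (-1.42) and Nlrp1a (2.67, SE 0.45), and of 26 splicing factors Rbfox2 passed (2 adjusted over the list alone). Ptprc and Hnrnpll were not called in either subset, and Hnrnpll in memory CD4 cells was called without the narrow arrays. The own-spread test called 0 in both, with 1174 and 1193 genes at an unadjusted p under 0.05 in the F test and 199 and 289 called by Simes, and the F test made 113 and 94 false calls on simulated data. Fitted to all 48 arrays the own-spread test called 5 genes in memory CD4 cells, namely Thada, Nfam1, Marco, Gfra2 and Acp2 (chosen after their values were seen), and 0 in memory CD8 cells.

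**Figure D2:**
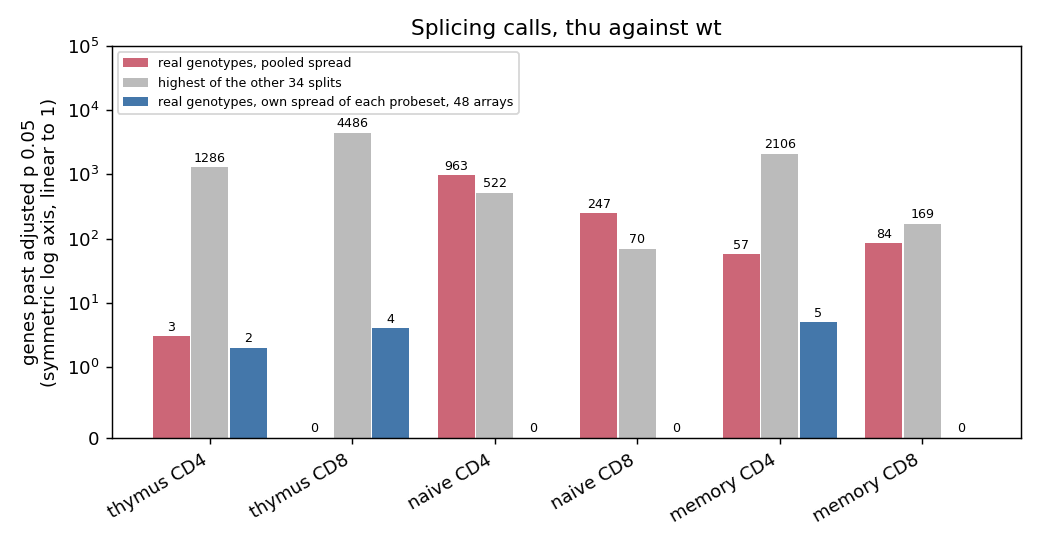
Genes called by the splicing F test in each comparison (symmetric log axis) for the real grouping, for the highest of the other 34 groupings of the same arrays, and with the own-spread test over all 48 arrays. The real grouping gives 963 genes in naive CD4 against 522 at most otherwise, and 57 in memory CD4 against 2106.

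The third question was how memory (CD44hi) cells differ from naive (CD44lo) cells in wt mice. Marker genes of other cells are among the rises below, so not every rise need come from T cells. In memory CD4 cells the chemokine receptor Ccr2 rose relative to the median change of all clusters by 5.44 (9.73 ± 0.79 against 4.55 ± 0.34 as deposited; SE 0.51, limma adjusted p = 6.06e-09), Cxcr3 by 5.02, Cxcr6 by 5.01, the inhibitory receptor Klrg1 by 4.78 and the interleukin 18 receptor gene Il18rap by 4.23. S100a6 and Anxa1 rose by 4.27 and 4.19, and the granule gene Nkg7 by 18.3-fold. Siglech, a lectin of plasmacytoid dendritic cells, rose by 5.34 and Cd209d by 4.58, with an SD of 2.26 and 2.33 among the memory arrays. Amigo2 changed by -1.97, Igfbp4 by -1.95, the adenylyl cyclase Adcy6 by -1.83, Als2cl by -1.79, Ggt5 by -1.75, Tmie by -1.75, the betaglycan gene Tgfbr3 by -1.72, Rnf32 by -1.72, Arhgap29 by -1.71 and Pdlim4 by -1.67 (adjusted p = 0.128 for Pdlim4 after quantile normalization). Ptprc and Hnrnpll differed by -0.061 and 0.41 (-0.32 and 0.15 as deposited) and were not called.

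In the CD4 lists 19 of 29 memory and effector genes rose and none fell (22 adjusted over the list alone; median 2.41, camera adjusted p = 1.86e-42), among them Gzmb (3.26), Ifng (3.05), Tbx21 (2.84) and Cd44 (2.37). Of 14 naive T cell genes 8 fell, with Lef1 (-1.31), Actn1 (-1.25), Ccr7 (-1.23) and Bach2 (-1.18), and Ccr9 rose (11 fell adjusted over the list alone; median -0.69, adjusted p = 0.00258; adjusted p = 0.593 with an estimated correlation). Of 13 follicular helper and exhaustion genes 6 rose, with Nrn1 (3.41), Lag3 (2.87), Cd160 (2.78) and Pdcd1 (2.30), and 9 adjusted over the list alone (median 1.49, 1.21e-12). Of 11 regulatory T cell genes Itgae (2.58) and Icos (1.70) rose, 2 adjusted over the list alone (median 0.71, 1.99e-05; adjusted p = 0.477 with an estimated correlation). Of 27 cell cycle genes 7 rose, with Mki67 (3.39) and Top2a (2.80), 9 adjusted over the list alone and 2 after quantile normalization (median 1.16; adjusted p = 0.665 with an estimated correlation). Of 28 T cell receptor signalling genes 9 fell (12 adjusted over the list alone), with Cd247 (-0.92) and Prkcq (-0.72), while 1 rose and 3 fell after quantile normalization, and the list as a whole was not called (adjusted p = 0.0758).

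Marker genes of other cells also rose with memory in CD4 cells. They were 11 of 12 myeloid genes (Tyrobp 3.89, Fcer1g 3.65, Csf1r 3.43 and Adgre1 3.43; median 2.66, 2.39e-25), 7 of 9 dendritic genes (with Ccr9 3.76, Irf8 3.66 and Clec9a 3.63; median 3.39, 7.06e-13) and 8 of 9 NK and innate-like genes (with Ncr1 2.47 and Itga2 2.14; median 2.15, 1.78e-24; 9 adjusted over the list alone). Blnk rose among 15 B cell genes (2.21; list median 1.54, 2.26e-09; adjusted p = 0.640 with an estimated correlation). Ccr6 (2.16) and Il23r (1.11) rose among 6 gamma delta genes (median 0.70, 0.00418; adjusted p = 0.103 with an estimated correlation). Nkg7 rose among 8 CD8 lineage genes (0.0238; adjusted p = 0.878 with an estimated correlation), and Vcam1 (3.12), Epcam and Cdh5 rose and Pecam1 fell among 9 stroma genes (0.0196; adjusted p = 0.665 with an estimated correlation). None of 7 erythroid genes passed, though the list was called (median 0.68, 0.00521; adjusted p = 0.688 with an estimated correlation), and none of 7 CD4 lineage genes did (list adjusted p = 0.879).

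The remaining CD4 lists were not called. In the immature thymocyte list (adjusted p = 0.313) Ccr4 rose, and in the mature thymocyte list (0.159) Ccr7 and S1pr1 fell. Ptbp1 fell among 19 hnRNP genes (change -0.37; 0.167) and Celf1 among 25 splicing factors (0 adjusted over the list alone; 0.156). Of 20 genes spliced alternatively in T cells 2 rose and 5 fell (0.958; median -0.13, though the test leaned upward). Pmaip1 rose and Bcl2 and Bcl2l11 fell among 20 apoptosis genes (0.175), Mx1 and Bst2 rose and Oas2 and Ifit2 fell among 20 interferon genes (0.0923), Gadd45b rose among 21 immediate early genes (0.187) and Rps18 fell among 8 ribosomal genes (0.267; 2 adjusted over the list alone). After quantile normalization no hnRNP, splicing factor or ribosomal gene passed, and no interferon or stroma gene fell. In all 13 lists passed with the preset and 5 with an estimated correlation, namely the memory and effector (adjusted p = 6.73e-05), follicular helper (0.00235), myeloid (0.00256), dendritic (0.00256) and NK lists (4.81e-06). With the replicate block and an estimated correlation the memory and effector list kept its call, and the follicular helper (0.0668), myeloid (0.0895), dendritic (0.199) and NK lists (0.0895) did not. The block with the preset added the mature thymocyte (0.0207), splicing factor (0.0207) and apoptosis lists (0.034), and these did not hold with the block and an estimated correlation (adjusted p = 0.378, 0.582 and 0.378).

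Of all clusters in CD4 cells 889 rose and 2219 fell before the median shift is taken into account, 3108 in all, with 6307 at an unadjusted p under 0.05. After quantile normalization 1042 rose and 254 fell, so the share of rises went from 28.6% to 80.4%, and 1082 clusters were called both ways. The replicate numbers paired these arrays, and limma with the block, fitted to the compared groups, called 7867 clusters (1319 higher and 6548 lower) against 6494 without it (1146 and 5348), of which 16.8% and 17.6% were higher.

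In memory CD8 cells the nuclease gene Dnase1l3 rose by 5.64 relative to the median change (9.77 ± 0.32 against 4.33 ± 0.52 as deposited; SE 0.66, limma adjusted p = 5.73e-07). Clec9a, a lectin of dendritic cells, rose by 5.20 and Irf8, a transcription factor of dendritic cells, by 4.38. Plbd1 rose by 5.39, Gpr141b by 4.91, S100a6 by 4.87, the cytokine signalling inhibitor Socs2 by 4.71, Pld4 by 4.69, Apol7c by 4.56 and Ifi205 by 4.44. Igfbp4 changed by -2.32, Tmie by -1.78, Tgfbr3 by -1.75, Tdgf1 by -1.68, Xkrx by -1.64, St8sia1 by -1.56, Lrrc75b by -1.55, Rgcc by -1.39, Amigo2 by -1.35 and Kcnmb4 by -1.35. After quantile normalization St8sia1 and Amigo2 were not called (adjusted p = 0.257 and 0.0621). Ptprc and Hnrnpll differed by 0.20 and 0.13 (-0.0028 and -0.064 as deposited) and were not called.

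In the CD8 lists 13 of 29 memory and effector genes rose (17 adjusted over the list alone; median 2.10, camera adjusted p = 1.95e-41), with S100a6, S100a4 (3.85), Gzmb (3.68) and Ccr2. Havcr2 (3.14), Cxcr5 (2.60) and Lag3 (2.09) rose in the follicular helper and exhaustion list (4 adjusted over the list alone and 2 after quantile normalization, without Cxcr5; median 0.81, 7.62e-09), and Fasl (2.17) and Pmaip1 (1.63) in the apoptosis list (median 0.41, 7.37e-05). Lef1 fell by 0.85 in the naive list (median -0.30, 0.0347; adjusted p = 0.809 with an estimated correlation). Mki67 rose by 2.79 in the cell cycle list (2 adjusted over the list alone; median 1.03, 3.4e-14; adjusted p = 0.640 with an estimated correlation), and its own call was lost after quantile normalization (adjusted p = 0.169). Cd44 and Itgb1 rose and Lef1 fell among alternatively spliced genes (0.0474; adjusted p = 0.930 with an estimated correlation, and 0.126 with the replicate block).

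Markers of other cells rose with memory in CD8 cells too. They were 9 of 12 myeloid genes (11 adjusted over the list alone; median 3.01, 5.3e-35), 4 of 9 dendritic genes (7 adjusted over the list alone; median 2.41, 1.98e-16), 7 of 9 NK genes (median 2.02, 4.22e-30), and Blnk and Cd22 among 15 B cell genes (12 adjusted over the list alone and 1 after quantile normalization; median 2.39, 7.35e-20; adjusted p = 0.107 with an estimated correlation). Cd163l1 rose among gamma delta genes (2.63; 3 adjusted over the list alone; list 0.00343; adjusted p = 0.0972 with an estimated correlation), and the erythroid list was called without any member (0.00343; adjusted p = 0.665 with an estimated correlation). Socs2 rose in the regulatory T cell list (0.270), Mx1 in the interferon list (0.156), Gadd45b in the immediate early list (0.156) and Vcam1 (2.80) in the stroma list (0.213), and these lists were not called. No member passed in the immature thymocyte (0.386), mature thymocyte (0.574), hnRNP (0.807), splicing factor (0.773), T cell receptor (0.242), ribosomal (0.692), CD4 lineage (0.153; 0.00369 with the replicate block, and adjusted p = 0.248 with the block and an estimated correlation) and CD8 lineage (0.239) lists.

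In CD8 cells 12 lists passed with the preset and 6 with an estimated correlation, namely the memory and effector (adjusted p = 6.73e-05), follicular helper (0.014), apoptosis (0.00318), myeloid (0.000409), dendritic (0.000645) and NK lists (9.27e-07). With the replicate block and an estimated correlation none of these 6 kept its call (adjusted p = 0.170, 0.0895, 0.202, 0.0668, 0.199 and 0.0895). Of all clusters 456 rose and 122 fell, 578 in all, with 2620 at an unadjusted p under 0.05. After quantile normalization 515 rose and 27 fell, with 443 called both ways, and the share of rises went from 78.9% to 95.0%. Limma with the replicate block on the compared groups called 1496 clusters (761 higher and 735 lower) against 1338 without it (729 and 609). The share of rises was then 50.9% and 54.5%, so it depends on the arrays in the fit as well as on the scale.

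**Figure D3:**
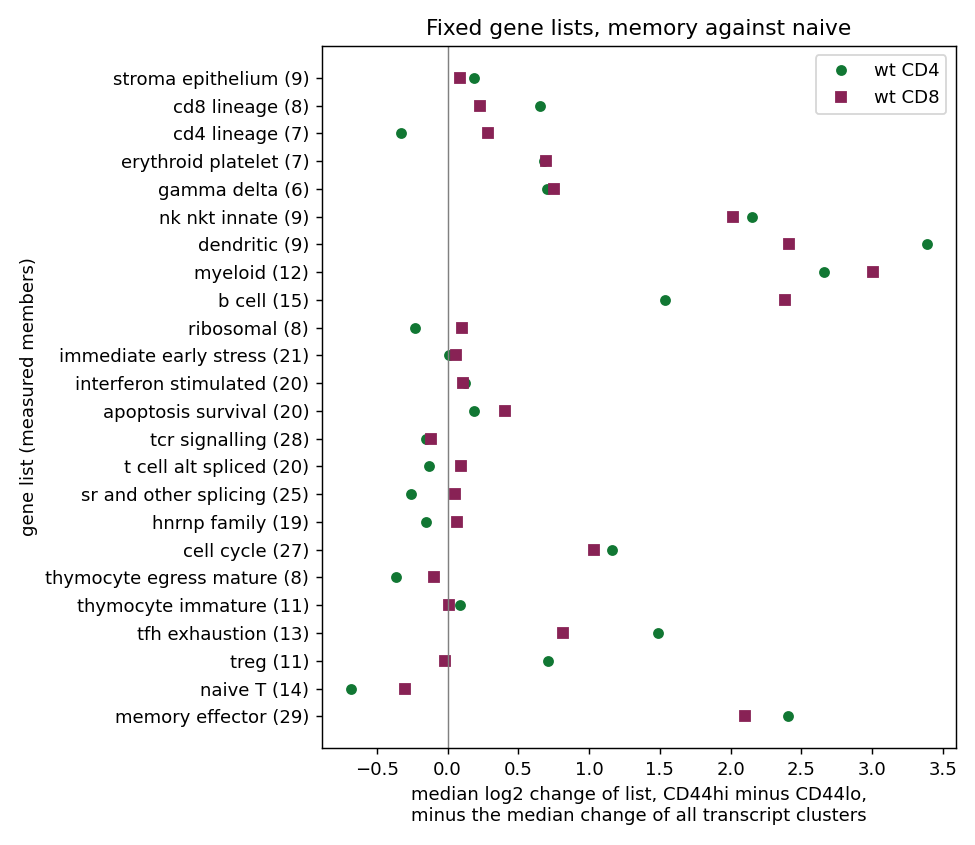
Median log2 change of each fixed list from naive to memory wt cells, relative to the median change of all clusters (horizontal axis), in CD4 and CD8 cells. Memory and effector genes lie at 2.41 in CD4 and 2.10 in CD8 cells, and naive T cell genes at -0.69 and -0.30.

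Probesets of the same gene also changed by unlike amounts between memory and naive wt cells. In CD4 cells the F test called 908 genes, led by the scavenger receptor Stab2 (deviation 2.63, SE 0.38), utrophin (Utrn, probeset 4669447, 3.33, SE 0.17, adjusted p = 1.92e-38) and Il18rap (-4.04, SE 0.21). Dst (1.35), the calcium release channel Ryr1 (2.85), Osbpl3 (-2.12), the complement gene C3 (-2.13), the mitotic kinesin Kif23 (1.99), Tbx21, which encodes T-bet (-3.16), and Atp8a2 (-1.92) followed. In CD8 cells 662 genes were called, led by the autophagy adaptor Wdfy3 (probeset 5288201, 2.98, SE 0.24, adjusted p = 4.64e-42), Lrrk1 (2.58), Nav1 (2.35) and Stab2 (2.67). Ppfibp2 (-2.35), Ttc39a (-2.18), the cation channel Trpm2 (2.61), Arhgap22 (3.37), the phagosomal transporter Slc11a1 (-3.13) and the metalloprotease Adam8 (-2.74) followed. Cd44 and Lef1 were called in both lineages, with Itgb1 in CD4 and Ctla4 in CD8 cells, of 27 genes spliced alternatively in T cells. Ptprc and Hnrnpll were not called. Of 32 memory and effector genes 14 were called in CD4 and 13 in CD8 cells (14 and 15 adjusted over the list alone), and of 27 cell cycle genes 11 and 15. Of 12 NK and innate-like genes 6 were called in each lineage, and in CD8 cells 6 of 14 myeloid genes (with Csf1r and Itgam) and 5 of 11 dendritic genes (with Flt3 and Xcr1). Of the called genes 49.3% in CD4 and 60.3% in CD8 cells had changed over 2-fold as a whole, against 7.11% and 4.74% of those tested, and without genes changed by over 1 log2 the counts were 381 and 204. The genes named here with a negative deviation all rose as a whole, and the other named probesets deviated upward. All Il18rap probesets together changed by 4.19 and those of Tbx21 by 2.81 in CD4 cells, and those of Slc11a1 by 3.00 in CD8 cells. A probeset that does not follow the amount of its gene would give this too, so these deviations are not taken as splicing. The own-spread test called 602 and 429 genes and shares this limit.

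The last question was whether thunder alters the step from naive to memory cells. At the gene level limma called 0 clusters in CD4 and 0 in CD8 cells for genotype by memory, with 223 and 244 at an unadjusted p under 0.05 and 0 in each after quantile normalization. The preset test called 7 lists in CD4 cells, namely regulatory T cell genes (median -0.90 relative to all clusters, camera adjusted p = 0.000497; adjusted p = 0.645 with an estimated correlation), NK (-0.31; adjusted p = 0.300 with an estimated correlation), memory and effector (-0.31), cell cycle (-0.36), follicular helper (-0.37), interferon (-0.21) and ribosomal genes (0.41). In CD8 cells it called NK genes (-0.61, 1.99e-05; adjusted p = 0.0646 with an estimated correlation), myeloid (-0.66; adjusted p = 0.730 with an estimated correlation), dendritic (-0.65; adjusted p = 0.645 with an estimated correlation), stroma (-0.34) and hnRNP genes (0.18). No call held with an estimated correlation and no member passed. With the replicate block, added to the list tests after the results were seen and adjusted over the 2 lineages, NK genes in CD4 cells were not called with the preset (adjusted p = 0.0639). The block added B cell genes, upward in CD4 and downward in CD8 cells (0.0422 in each), and cell cycle genes, downward in CD8 cells (0.0069). No list held with the block and an estimated correlation (lowest adjusted p = 0.634, also the value for NK genes in CD8 cells). The splicing F test called 0 genes in each lineage, with 73 and 151 at an unadjusted p under 0.05. Simes called 3 and 2, the own-spread test 0 and 0, and the F test with the replicate block 4 in CD4 cells, whose arrays the numbers paired. On simulated data the F test recovered 34 and 33 of 100 genes changed by 2 log2, with 42 and 69 false calls, so these counts do not exclude such changes.

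Ptprc was also compared over all subsets, in a test chosen after its values were seen. Of its 35 probesets 4 lay higher in thu than in wt, relative to the other probesets of the gene, in all 6 subsets. They are 4667430 (mean deviation 0.97, from 0.57 to 1.49), 4665271 (0.81, from 0.65 to 1.02), 4615486 (0.64, from 0.26 to 1.21) and 4593278 (0.27). Here the mean deviations and the array values below are relative to the mean of all 35 probesets, and the ranges relative to the other probesets. A further 5 lay lower in all 6 subsets, namely 5256007 (mean deviation -0.31, from -0.47 to -0.21), 5199340 (-0.27), 5065221 (-0.17), 4518366 (-0.12) and 5552554 (-0.11). In thymus CD4 arrays 4667430 lay at 1.36 ± 0.35 in thu and -0.090 ± 0.16 in wt, and in memory CD8 arrays at 1.09 ± 0.13 and 0.54 ± 0.29. Apart from the first 3, the mean deviations lay between -0.37 and 0.27. Which exons these probesets cover is not known here.

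**Figure D4:**
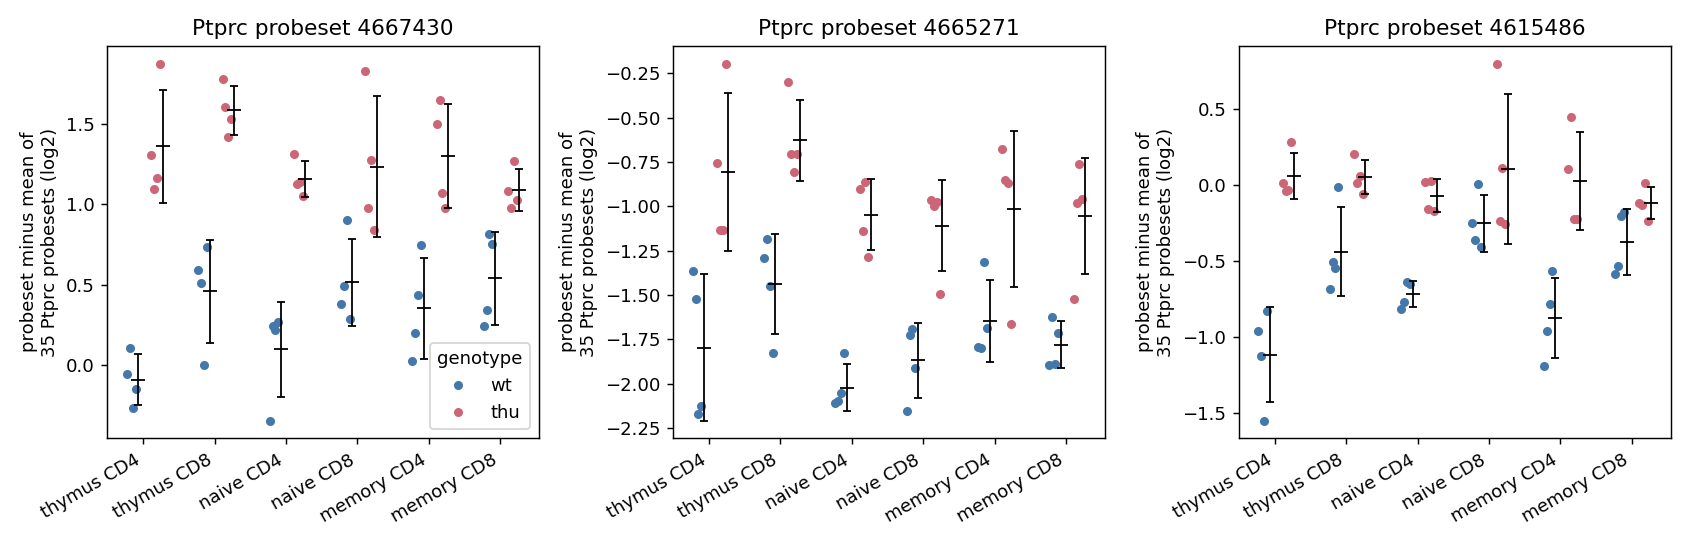
Log2 signal of 3 Ptprc probesets minus the mean of all 35 Ptprc probesets on the same array (vertical axis), per array and as mean ± SD of 4 arrays, in thu and wt cells of the 6 subsets. All 3 have a higher mean in thu in all 6 subsets, by 0.57 to 1.49 for 4667430 relative to the other probesets.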

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

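Of the tests in this part, the own-spread test, the fits without narrow arrays and the tests on a variant linked to Acp2 and Rnf32, on the normalization of marker genes and on cells within the CD44hi gate were chosen after results were seen. The following values each come from 1 array that lies far from the other 3 of its group. They are 14 of 299 groups tested, where chance alone would give 14.95, about 1 in 20.

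At the gene level Ptprc was 11.29 in thu naive CD8 replicate 1, against 12.13 to 12.25 in the others. Hnrnpll was 7.89 in thu memory CD8 replicate 1 (others 6.80 to 6.85), and Dnase1l3 was 3.56 in wt naive CD8 replicate 3 (others 4.52 to 4.63). The rest are probesets relative to the mean of their gene. Hnrnpll 4889875 was 3.66 in wt thymus CD4 replicate D (others 2.74 to 2.76). In wt naive CD4 arrays Ncor1 5502165 was -1.91 in replicate 1 (others -2.81 to -2.68), Eif4g1 4531764 was 0.27 in replicate 2 (others -1.96 to -1.62) and Ptprc 4667430 was -0.34 in replicate 1 (others 0.22 to 0.27). In thu naive CD8 arrays Tle1 5234161 was 1.22 in replicate 1 (others 0.25 to 0.40) and Ptprc 4665271 was -1.49 in replicate 4 (others -0.9996 to -0.96). In wt memory CD4 arrays Zmym3 4378121 was -1.27 in replicate 1 (others 0.39 to 0.71), Il18rap 5094403 was -4.28 in replicate 4 (others -5.19 to -5.11) and Kif23 5425738 was 0.90 in replicate 1 (others 0.56 to 0.58). In replicate 1 of the same group Tbx21 4697461 was 4.93 (others 4.34 to 4.42) and Atp8a2 4597028 was -2.28 (others -3.11 to -3.05).

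Splicing called 963 genes between thu and wt naive CD4 cells. Leaving out the 2 thu arrays of narrow spread gave 153, and leaving out the other 5 pairs of thu arrays gave 125 to 7150 with a median of 965. The highest count came without thu 3 and 4, which keeps only the narrow pair. The lowest came without thu 1, which is narrow, and thu 4, while the count without thu 1 and 3 was 1230. Leaving out the narrow pair thus lowered the count and keeping only that pair raised it, though leaving out 1 other pair lowered it further. Narrow spread therefore cannot be told apart from other differences between the arrays as a cause. No other of the 35 groupings of the arrays gave as many, with 522 at most. A share of 1 in 35 is the smallest that these groupings can give. It was not adjusted over the comparisons, so chance in how the arrays fall into groups is not excluded. The own-spread test called 0, so unequal noise of the probesets stays open, as does an effect of thunder on splicing.

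Acp2 and Rnf32 were lower in thu in several subsets, and so was a probeset of Thada. A variant within Acp2 or Rnf32 carried along with the Hnrnpll mutation by linkage is excluded, since 0 of the 2 genes lie on the chromosome of Hnrnpll. A linked variant elsewhere on that chromosome could still act on them, and the positions of the genes cannot test that. Arrays of narrow spread are excluded for Acp2, since its larger limma adjusted p without them in naive and memory CD4 cells was 0.00885. Thada lies 75 genes from Hnrnpll in the GRCm38.p6 gene table. Of 90 probesets lower in several subsets 1, this Thada probeset itself, lies in the stretch of 100 genes on each side (Fisher's exact test, two-sided, p = 0.3598). A test over many probesets cannot show whether 1 gene carries a variant. A linked variant under this probeset therefore cannot be told apart from a change of splicing. An unlinked difference between the strains, a linked variant that acts from a distance and an effect of thunder stay open for Acp2 and Rnf32 and were not tested.

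Dendritic and myeloid marker genes were higher in wt CD44hi than in CD44lo cells of both lineages, although the sort was on CD4, CD8 and CD44 and no stain against these cells is named. Separate normalization is excluded as the whole cause, since 31 of 31 calls of these genes were kept after quantile normalization. Cells of these types within the CD44hi gate may be a source, and 4 of 5 abundant transcripts (Cd74, H2-Aa, H2-Ab1 and Tyrobp) were higher by over 1 log2 in both lineages. Only Tyrobp passed the gene-level test, and Cd74 did not (adjusted p = 0.344 in CD4 and 0.105 in CD8 cells), nor did H2-Aa or H2-Ab1. Cd74 was 12.4 in memory and 11.2 in naive CD4 cells and 12.6 and 9.90 in CD8 cells, and Tyrobp was 10.3 and 6.71, and 9.39 and 5.22, while Ctss (11.8 in naive CD4 cells) was higher by 0.63 and 0.50 only. Because Ctss starts high, its small rise does not decide between such cells and expression by memory T cells. Both fixed lists of markers of these other cells rose as sets. With an estimated correlation camera gave an adjusted p of 0.00256 for each in CD4 cells, and 0.000409 (myeloid) and 0.000645 (dendritic) in CD8 cells. The rise of these lists is the pattern to be explained, and expression by memory T cells would give it too. The list tests therefore do not decide between the sources. The list calls did not hold with the replicate block and an estimated correlation (lowest adjusted p = 0.0668).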

How the results depend on the processing

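The own-spread test, splicing without genes changed by over 1 log2 and the fit without narrow arrays were chosen after the data were seen. Of the counts that answer a comparison, 187 under alternatives fixed beforehand and 12 under added ones stayed within 1.5 times the reported value, and 125 and 24 did not. Of the values of named genes 1880 and 127 kept their direction and their side of the threshold, 211 and 87 became weaker, 22 and 5 reversed and 4 and 2 became stronger. The cause was not tested for any change, except that leaving out arrays or filters changes what is tested. Low signals limit both levels, and the clusters called between thu and wt naive CD4 cells have a median log2 mean of 3.45, near the filter at 3.

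Gene-level counts were as follows. A mean above 5 gave 1 in naive CD4, 15 in naive CD8, 2 in memory CD8, and 1801 and 332 for memory against naive in CD4 and CD8. Quantile normalization gave 2 in thymus CD4, 15 in naive CD4, 7 in naive CD8, 2 in memory CD8 and 1296 for memory against naive in CD4. The compared groups alone gave 0 in thymus CD4, thymus CD8, naive CD8 and memory CD8, 6 in naive CD4 (3 higher and 3 lower), and 6494 and 1338 for memory against naive. With the replicate block they gave 0 in all 6 genotype comparisons, and 7867 and 1496 for memory against naive. Without narrow arrays 4 passed in naive CD4, 5 in naive CD8 and 5 in memory CD4 (4 higher and 1 lower).

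Splicing counts moved more. No filter gave 1 in thymus CD8, 97 in memory CD4, 132 in memory CD8 and 1 for genotype by memory in CD4. A mean above 5 gave 0 in thymus CD4, 602 in naive CD4, 98 in naive CD8, 22 in memory CD4, 31 in memory CD8, and 398 and 289 for memory against naive. Quantile normalization gave 125 in memory CD4 and 1 for genotype by memory in CD4. All 48 arrays gave 6, 3, 25, 129, 5 and 4 in thymus CD4, thymus CD8, naive CD4, naive CD8, memory CD4 and memory CD8, and 439 and 310 for memory against naive. The replicate block gave 5 in thymus CD4, 1 in thymus CD8, 572 in naive CD4, 12 in memory CD4, and 4 and 3 for genotype by memory. Simes gave 5, 2, 478, 199 and 289 in thymus CD4, thymus CD8, naive CD8, memory CD4 and memory CD8, and 3 and 2 for genotype by memory. An analysis of variance without moderation, pooled within gene, gave 1 in thymus CD4.

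The own-spread test gave 0 in thymus CD4, naive CD4, naive CD8, memory CD4 and memory CD8, and 602 and 429 for memory against naive. Over all 48 arrays it gave 4 in thymus CD8, 0 in naive CD4, naive CD8 and memory CD8, 5 in memory CD4, and 454 and 357 for memory against naive. Without narrow arrays the F test gave 1 in thymus CD4, 1 in thymus CD8, 153 in naive CD4, 18 in memory CD4 and 2 for genotype by memory in CD4. Without genes changed by over 1 log2 it gave 381 and 204 for memory against naive. Where the numbers pair the arrays the block changed no other count by over 1.5 times. In the other subsets not every pair exceeded 0.1, and the lowest gene-level correlation of same-numbered arrays was -0.023 in thymus CD4, -0.15 in naive CD4, -0.058 in naive CD8, -0.23 in memory CD4 and -0.12 in memory CD8. In thymus CD4 it was pair C alone that failed, as pairs A, B and D correlated at 0.50, 0.64 and 0.45, so pairing of the others there stays open.

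Leaving out each array gave gene-level counts of 1 to 2 in thymus CD4, 1 to 3 in thymus CD8, 13 to 293 in naive CD4, 5 to 250 in naive CD8, 1 to 11 in memory CD4 and 1 to 7 in memory CD8. They were 1827 to 2647 and 387 to 511 for memory against naive, and 0 to 1 in each lineage for genotype by memory. Splicing gave 1 to 6, 0 to 2, 178 to 3095, 30 to 489, 0 to 329 and 20 to 221 in the same order of subsets, 544 to 1160 and 490 to 667 for memory against naive, and 0 to 1 in each lineage for genotype by memory.

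At the gene level the following arrays moved a count by over 1.5 times. Without thu D or wt D thymus CD4 gave 2, and without thu D thymus CD8 gave 3. Naive CD4 gave 22, 13 and 293 without thu 1, 2 and 3, and 23 and 22 without wt 2 and 4. Naive CD8 gave 5, 6 and 250 without thu 1, 2 and 3, and 6, 24 and 27 without wt 2, 3 and 4. Memory CD4 gave 3 and 11 without thu 4 and wt 4. Memory CD8 gave 2, 1 and 7 without thu 1, 2 and 4, and 1, 2 and 1 without wt 1, 2 and 3. Memory against naive CD4 gave 1827 without wt naive 4. Genotype by memory gave 1 without wt naive 2 in CD4 and 1 without thu memory 4 in CD8.

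For splicing, thymus CD4 gave 1 without thu A or any wt array and 6 without thu D, and thymus CD8 gave 1, 2 and 1 without thu C, thu D and wt D. Naive CD4 gave 178, 312, 3095 and 1689 without thu 1 to 4, and 199, 294, 482 and 239 without wt 1 to 4. Naive CD8 gave 133 and 489 without thu 2 and 4, and 91, 63, 66 and 30 without wt 1 to 4. Memory CD4 gave 10, 3, 298 and 229 without thu 1 to 4, and 1, 5, 0 and 329 without wt 1 to 4. Memory CD8 gave 20, 221 and 55 without thu 2, 3 and 4, and 30 and 37 without wt 2 and 3. Memory against naive CD4 gave 544 without wt naive 2. Genotype by memory gave 1 without thu memory 3 in CD4, and 1 without thu naive 4 or wt memory 1 in CD8.

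The values that reversed belong to Hnrnpll and Ptprc and were not called either way. Quantile normalization gave Ptprc 0.031 in thymus CD4 and -0.0075 for genotype by memory in CD8, and Hnrnpll 0.053 for memory against naive in CD8. Without narrow arrays Ptprc was 0.023 in thymus CD4, 0.053 in naive CD8 and -0.15 for genotype by memory in CD8, its probeset -0.23 there, and a Hnrnpll probeset 0.28 in naive CD4. Leaving out each array gave Ptprc -0.16 to 0.14 in thymus CD4, -0.27 to 0.053 in naive CD8, -0.032 to 0.16 for genotype by memory in CD4 and -0.15 to 0.17 in CD8, with its probeset at -0.23 to 0.97. In the comparison called Ptprc gene-level memory vs naive, wt CD8 it gave -0.077 to 0.050. It gave Hnrnpll -0.24 to 0.53 in naive CD4, -0.052 to 0.85 in memory CD4 and -0.24 to 0.76 for genotype by memory in CD4.

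The arrays of each comparison were also split in each of the 35 ways into 4 and 4 (for genotype by memory, 35 regroupings), and the splits with a count as large as the real one were counted, the real one included. The rule set beforehand asked for a share of splits under 0.05, and 1 of 35 is the smallest share possible. No adjustment was made over the comparisons, so passing this rule does not exclude chance. At the gene level naive CD8 passed it (1 split, 49 against 2 at most in the others). Memory against naive also had 1 split in each lineage (3108 against 292 in CD4 and 578 against 1 in CD8). The rule was not passed for thymus CD4 (13 splits, 1 against 161), thymus CD8 (17 splits, 1 against 8922), naive CD4 (2 splits, 77 against 112), memory CD4 (13 splits, 1 against 179), memory CD8 (3 splits, 4 against 23) or genotype by memory (35 splits each, 0 against 18 and 0 against 0). For splicing naive CD4 (1 split, 963 against 522) and naive CD8 (1 split, 247 against 70) passed it, and memory against naive had 1 split each (908 against 19 and 662 against 401). The rule was not passed for splicing in thymus CD4 (13 splits, 3 against 1286), thymus CD8 (35 splits, 0 against 4486), memory CD4 (6 splits, 57 against 2106), memory CD8 (5 splits, 84 against 169) or genotype by memory (35 splits each, 0 against 10 and 0 against 2). Splits with several times the real count, in the thymus subsets and memory CD4 at both levels and in memory CD8 at the gene level, point to some structure of the samples. What these splits separate was not tested. Among the 8 splits that part every pair, thymus CD8 had 1 as large at the gene level and 8 for splicing, with 0 at most in the others, and memory against naive had 1 in each lineage at both levels. Where the numbers pair the arrays only these 8 splits count, and the smallest share, 1 of 8, is above 0.05. For memory against naive this test therefore cannot exclude chance. The others gave at most 1 in CD4 and 0 in CD8 at the gene level, and 11 and 3 for splicing. Thymus CD4, where 1 pair failed the check, would have 1 at each level, with 0 at most in the others at the gene level and 1 for splicing.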

Other observations

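The Ptprc tests in this part were chosen after its values were seen. Ptprc encodes CD45, and skipping of its variable exons is the best known event that Hnrnpll regulates. A candidate explanation for its probesets is that thu cells include more of some Ptprc sequence in all subsets together. Permuting genotype within subsets gave p = 1e-05 for probesets 4667430 and 4665271, the smallest that 1e+05 permutations can give, and 3e-04 for 4615486, each set against the largest mean deviation over all 35 probesets. That test takes the subsets as independent, although the numbers tie some naive and memory arrays to each other. A second permutation test moved the labels of same-numbered arrays together over the 4 naive and memory subsets, and over the 2 thymus subsets. Its 4900 permutations gave p = 0.000408 for 4667430, the smallest value they can give, 0.00122 for 4665271 and 0.0192 for 4615486. It did not keep same-numbered thu and wt thymus arrays as pairs, although the numbers were taken to pair them in thymus CD8 cells. With those pairs kept, fewer permutations remain and the smallest possible p is higher, and this was not run. The hypothesis held in both tests, on the data it was found in. The 5 probesets lower in all 6 subsets did not stand out in this permutation test, with p = 0.608 or more. Where the probesets lie was not known, so inclusion of the variable exons was not tested, and probes that respond to a sequence variant stay open.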
